A study of Mus musculus with 8 samples.

How the data were processed

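Liver RNA of 9-month-old mice was compared on 8 two-colour Agilent arrays, 4 with untreated Wrn mutants and 4 with vitamin C treated Wrn mutants, each against wild type liver RNA. The labels give total RNA, the strain C57Bl/6 in both channels, food and water without limit and a reversed light cycle of 12 h light and 12 h dark. The dose and duration of the vitamin C treatment are not given in the sources used here. The series design describes 4 independent biological replicates with a dye swap on replicates 3 and 4 of each group.

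The authors deposited a table of log ratios for 45220 features, read here as log2 values, and per the submitters' processing notes limma was used, with no role or version stated. Background correction, normalization, log base and direction are not given in the sources used here. Array medians between -0.01 and 0.00 show that the deposited values were centred. The table holds no intensity, so dim or saturated features could not be left out and control features could not be told from others. It has no missing value. GEO's platform annotation gave a single gene symbol for 33653 features, several for 56 and none for 11511. The Entrez numbers of 33517 features were found in a table of RefSeq genes of the assembly GRCm38, and no symbol needed updating. Features of a gene were averaged, which gave 19087 genes, 8343 of them with more than 1 feature. No genome build is named in the files, so the RefSeq table was used only for names and for the order of genes.

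The values had been planned to be read as Cy5 over Cy3 and turned by the dyes in the labels, with values already turned as the listed alternative. The plan rested on the array titles, which name the Cy5 RNA first on swapped and unswapped arrays alike. The alternative was taken after the data were seen, from a count of genes beside Wrn. Of the 100 measured genes on each side of Wrn, 17 had an unadjusted p under 0.01 for both groups over wild type with the values as deposited, and 0.852% of 15031 such windows held as many. With the values turned by the dyes, 9 did, and 57.2% of windows held as many. Over all genes the counts ran the other way, with 414 genes at that p as deposited and 889 turned by the dyes. As this count chose the reading, it is no independent evidence of a change near Wrn. Deposited values had a median of 15 significant digits on the unswapped arrays and 6 on the swapped ones, so the 2 kinds of column differ in how they were written. Turning the swapped arrays exchanges the terms of the fit, so that the dye coefficient of each gene as deposited equals its mean change of both groups over wild type under the planned reading. That mean passed for 220 genes, 201 of them higher, with the wild type number as a block and for 309 without it, against 0 and 2 as deposited. The choice of reading thus decides this count. Under the planned reading 9, 10 and 0 genes passed in the 3 comparisons, and 9 of the 9 and 9 of the 10 were higher. At an unadjusted p under 0.05 there were then 1932, 1746 and 572 genes, against 1487, 1354 and 817 as deposited. Which genotype is the numerator is not settled by the sources and is taken as the mutant.

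Each comparison was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 over all 8 arrays, with a coefficient per group and a dye coefficient of opposite sign on swapped arrays, which left 5 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The dye coefficient passed that threshold for 371 genes, 309 of them above 0 and 62 below, with Ehhadh at 0.98 on the log2 scale (adjusted p = 0.00394) as an example. A coefficient above 0 means brighter in Cy5 if the values are mutant over wild type and brighter in Cy3 if they are the other way round. Values per array are printed after subtracting it. Gene lists, 35 of liver pathways, sex-biased genes, cell type markers and neighbours of Wrn, were fixed before the data were examined, as were the tests, the named-gene rule and the alternatives not marked otherwise, and tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. The genes named for each comparison are the 8 largest rises and 8 largest falls among those that pass, filled up where fewer pass with those of smallest p in each direction, then up to 3 members of smallest p per called list in its direction, and always Wrn, Gulo and Slc23a1. Features of 1 named gene disagreed in sign in the comparisons with wild type (Wrn, 1 of 4), and of Wrn and Slc23a1 between treated and untreated mutants, where the values lie near 0. Features of the same sign also differed in size, as for Fgl1, Ppp1r3c and Erdr1, and the SE of a gene does not show this. The median SE was 0.122 for each comparison with wild type and 0.173 between treated and untreated mutants.

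The replicate number was taken to pair the arrays, because the labels give the same wild type number on both arrays of a number, which was read as the same wild type animal. As a check, residual correlations across genes of the 2 arrays of a number were 0.00, 0.03, 0.24 and 0.20, against -0.50 to -0.33 between arrays of different numbers in the same dye orientation and 0.09 to 0.19 in opposite orientations, above numbers 1 and 2. The fit forces residuals to sum to 0 within a group and within an orientation, which lowers correlations within an orientation and raises those across. The pairing rests on the labels. The shared part was 0.328 of the residual variance. Fits with the number as a block are alternatives, with a random block (correlation 0.129) against wild type and a fixed block between treated and untreated mutants. The comparison of both groups averaged over wild type has the random block. Other alternatives were no dye coefficient, median centring, scale normalization, array weights, robust eBayes, each group's arrays alone, a test per feature, an adjusted p under 0.10 and leaving out each array in turn. Leaving out both arrays of a number, and the planned reading of the values for gene lists and for both groups averaged, were run only after seeing the data. The correlation and the overlap of genes expected from shared wild type RNA were taken from 50 simulations.

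The fits were tested on simulated data with the residual spread and dye effects of the real 19087 genes, a shared wild type part, and 100 genes changed 2-fold and 100 changed 4-fold. For untreated mutants over wild type 84% of the genes changed 2-fold and 96% of those changed 4-fold were recovered, and 22 of 202 calls were false, above the 5% aimed at. For treated mutants over wild type it was 83% and 99%, with 11 of 193 calls false, and between treated and untreated mutants 59% and 96%, with 5 of 160 false. The simulated genes varied independently, unlike real ones. A list shifted by 0.4 was called, and no other list was.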

Results

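Gene expression was measured in the liver of 9-month-old mice with a mutant Wrn protein, with and without vitamin C treatment, on 8 two-colour Agilent arrays. Wrn encodes a RecQ helicase, an enzyme that unwinds DNA. Each array set liver RNA of a mutant mouse against liver RNA of a wild type mouse. 4 arrays held untreated mutants and 4 held vitamin C treated mutants. In each group, the mutant RNA carried the dye Cy5 on replicates 1 and 2 and the dye Cy3 on replicates 3 and 4. The labels give the same wild type number on both arrays of a replicate number. The deposited table gave a log ratio for 45220 features on every array, from which 19087 named genes were tested. The median log ratio of the arrays lay between -0.01 and 0.00, and no intensity was given. The replicates are described as independent biological ones, and the number of arrays, 4 per group, limits the precision. Whether the values of the dye-swapped arrays had already been turned is not given in the sources used here. They were taken as turned, a choice made after the data were seen, and results turn on it. With the values turned by the dyes, the planned reading, 9, 10 and 0 genes passed in the 3 comparisons and 220 for both groups averaged over wild type, where the values as deposited gave 0. The direction is likely mutant over wild type. The basis is that wild type is the first channel on every array, that the series title sets mutants against wild type, and that the titles of unswapped arrays put the mutant, which is Cy5 there, first. The titles of swapped arrays put wild type, which is Cy5 there, first, as the planned reading of Cy5 over Cy3 has it. The array descriptions name wild type first, so the sign is not settled. If it is the other way round, every higher and lower value against wild type below changes places, and so do those between treated and untreated mutants. Values are means of dye-corrected log ratios ± SE with n = 4 arrays per group, read as log2 although the base is not given in the sources used here.

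The first comparison asked how the liver of untreated Wrn mutants differed from wild type liver. No gene passed the test in limma at an adjusted p of 0.05. The smallest adjusted p was 0.125. At an unadjusted p under 0.05 there were 1487 genes, 599 higher and 888 lower, where 5% of the genes tested is about 954. The genes with the smallest p, none of which passed, included Mapkapk2, a kinase of the p38 stress pathway, at -0.80 ± 0.09 and Slc25a15, the mitochondrial ornithine carrier, at -0.94 ± 0.12. Oat, the ornithine aminotransferase, stood at -0.82 ± 0.13. Plac9a stood at -0.98 ± 0.12, Syne3 at -0.78 ± 0.11, Lad1 at -0.96 ± 0.15, P2ry2, a receptor for extracellular nucleotides, at -0.58 ± 0.09, and Krt6b, a keratin, at -1.29 ± 0.18. On the other side, Mlkl, the effector of necroptosis, stood at 1.41 ± 0.24, a ratio of 2.65-fold. Fgl1, a protein secreted by hepatocytes, stood at 0.89 ± 0.12, the mean of features at 0.20 and 1.59. Mfhas1 stood at 0.76 ± 0.12 and S1pr1, a sphingosine-1-phosphate receptor of endothelial cells, at 0.85 ± 0.14. Spcs3, a subunit of the signal peptidase, stood at 0.63 ± 0.11, Ptgds, a prostaglandin D synthase, at 0.78 ± 0.14, Xiap, an inhibitor of caspases, at 0.56 ± 0.11 and Myh11, the smooth muscle myosin heavy chain, at 0.55 ± 0.11. Each of these 16 genes had the sign of its mean on 4 of 4 arrays, but genes chosen by smallest p tend to show this. Slc25a15, Fgl1, Mfhas1 and Spcs3 lie within 100 measured genes of Wrn, the window whose count chose the reading of the values. Wrn itself stood at 0.19 ± 0.10 over 4 features with an adjusted p of 0.698. The position of these features relative to the mutation is not given in the sources used here, and 1 of them had the opposite sign, so Wrn checks no label. Gulo, which makes the last step of ascorbate synthesis, stood at -0.24 ± 0.10, and the ascorbate transporter gene Slc23a1 at -0.13 ± 0.11.

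Of the 35 gene lists, 2 rose in the untreated mutants by limma's camera with its preset correlation of 0.01. The cholesterol synthesis list rose by a mean of 0.20 over 20 measured genes (adjusted p = 0.0246), with 14 members above 0 and 6 below. With an estimated correlation its adjusted p was 0.973. Its members with the smallest p were Hmgcs1, which makes HMG-CoA, at 0.61 ± 0.20, Sqle, the squalene epoxidase, at 0.66 ± 0.26 and Insig1, which holds back the SREBP pathway, at 0.62 ± 0.25. The ER stress and unfolded protein response list rose by a mean of 0.14 over 28 genes, 24 of them above 0 (adjusted p = 0.0184, and adjusted p = 0.973 with an estimated correlation). Ddit3, the stress transcription factor CHOP, stood at 0.71 ± 0.17, the chaperone gene Dnajb9 at 0.33 ± 0.15 and Pdia4, a protein disulfide isomerase, at 0.27 ± 0.16. No member of either list passed over all genes or adjusted over the list alone. Single arrays decided both calls. Without mutant replicate 1 the cholesterol mean was 0.14 (adjusted p = 0.181) and the ER stress mean was 0.03 (adjusted p = 0.564). Without mutant replicate 3 the cholesterol mean was 0.03 (adjusted p = 0.988), and without mutant replicate 4 the ER stress mean was 0.10 (adjusted p = 0.160). Named members moved with them. Without mutant replicate 1, Sqle stood at 0.38, Dnajb9 at 0.16 and Pdia4 at 0.07, and without mutant replicate 3, Hmgcs1 stood at 0.38, Sqle at 0.43 and Insig1 at 0.27. In the other direction, Hmgcs1 stood at 0.92 without mutant replicate 4, and Dnajb9 at 0.50 and Pdia4 at 0.42 without mutant replicate 2. Without both arrays of number 4, a setting chosen after the data had been seen, 15 genes passed, among them Slc25a15, Plac9a, Krt6b and Hmgcs1.

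The second comparison set vitamin C treated mutants against wild type. Again no gene passed in limma, with a smallest adjusted p of 0.363. At an unadjusted p under 0.05 there were 1354 genes, 711 higher and 643 lower. Without treated replicate 2, 3 genes passed, Cyp3a11 (-1.60) and Erdr1 (-3.01, both with an adjusted p of 0.0162) among them. Leaving out both arrays of number 2 was chosen after the data had been seen. Bcl6 (2.02) and Erdr1 (-3.07) then passed at 0.0120, and Cyp3a11 (-1.61) and Cyp17a1 (-1.42) at 0.0297. The genes with the smallest p, which did not pass with all arrays, included 2 sulfotransferases of steroids and bile acids. Sult2a2 stood at -2.30 ± 0.34, which is 4.91-fold lower, and Sult2a4 at -2.28 ± 0.37. Cyp3a11, the main hepatic cytochrome P450 of the 3a family, stood at -1.26 ± 0.20, the metallothionein gene Mt2 at -0.96 ± 0.15 and Erdr1 at -2.37 ± 0.39. Trmt9b stood at -1.68 ± 0.23, Tmem267 at -0.97 ± 0.16 and Onecut1, a hepatocyte transcription factor, at -0.78 ± 0.13. On the other side, Bcl6, a transcriptional repressor that acts on sex-biased liver genes, stood at 1.71 ± 0.26, which is 3.27-fold, and Cd163, the haptoglobin-haemoglobin receptor of macrophages, at 1.20 ± 0.17. Hes1, a target of Notch signalling, stood at 0.91 ± 0.17, Ppp1r3c, which directs a phosphatase to glycogen, at 0.72 ± 0.14 and Vegfc, a lymphatic growth factor, at 0.70 ± 0.13. The features of Ppp1r3c stood at 0.29 and 1.14, and those of Erdr1 at -3.65 and -1.10. Prxl2b stood at 0.81 ± 0.16, Mfhas1 at 0.61 ± 0.12 and Mrpl22, a mitochondrial ribosomal protein gene, at 0.46 ± 0.09. All 16 had the sign of their mean on 4 of 4 arrays, but genes chosen by smallest p tend to show this. Trmt9b, Vegfc and Mfhas1 lie within 100 measured genes of Wrn, the window whose count chose the reading of the values. Wrn stood at 0.16 ± 0.10, Gulo at -0.34 ± 0.10 and Slc23a1 at -0.21 ± 0.11. The pairs Sult2a2 and Sult2a4, and the Cyp3a and metallothionein genes, are close paralogs whose features may bind RNA of each other, so the single members are uncertain.

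In the treated mutants, 9 lists shifted against wild type by camera with the preset correlation, and none did with an estimated correlation. The female-biased liver genes fell by a mean of 0.45 over 25 genes (mean log2 ratio -0.45, adjusted p = 3.8e-06, and adjusted p = 0.293 with an estimated correlation), with 19 members below 0. 4 of them passed adjusted over the list alone and none over all genes. Besides Sult2a2, the leading members were Cyp3a16 at -0.74 ± 0.14 and Cyp17a1, a steroid hydroxylase, at -1.04 ± 0.22. The male-biased liver genes rose by a mean of 0.19 over 22 genes (adjusted p = 0.00146, and adjusted p = 0.927 with an estimated correlation), with 17 above 0 and 1 passing adjusted over the list alone. Susd4 stood at 0.72 ± 0.17, the organic anion transporter gene Slco1a1 at 0.30 ± 0.10 and Gstp1, a glutathione transferase gene, at 0.54 ± 0.19. The xenobiotic metabolism list, which shares 8 genes with the female-biased list, fell by a mean of 0.19 over 45 genes (mean -0.19, adjusted p = 0.0211, and adjusted p = 0.927 with an estimated correlation). Its median was -0.06, 3 members passed adjusted over the list alone, and its leading members were Cyp3a11, Cyp3a16 and Cyp3a41a, the last at -1.56 ± 0.33. The cholesterol synthesis list fell by a mean of 0.21 (mean -0.21, adjusted p = 0.00157, and adjusted p = 0.927 with an estimated correlation). Of its 20 genes 16 lay below 0 and 1 passed adjusted over the list alone. Hsd17b7 stood at -0.61 ± 0.11, Sqle at -0.68 ± 0.26 and Cyp51 at -0.35 ± 0.14.

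Markers of Kupffer cells and macrophages rose in the treated mutants by a mean of 0.50 over 18 genes (adjusted p = 0.00146, and adjusted p = 0.927 with an estimated correlation). 2 members passed adjusted over the list alone. Clec4f, a lectin of Kupffer cells, stood at 0.90 ± 0.20 and Vsig4, a complement receptor, at 1.13 ± 0.41. The list's mean was 2.25 on treated replicate 4 and -0.93 on treated replicate 3, and without treated replicate 4 it was -0.20 (adjusted p = 0.896), with Clec4f at 0.56 and Vsig4 at 0.47. Vsig4 stood at 1.69 without treated replicate 3. Without both arrays of number 4 the list was called in the opposite direction (mean -0.30, adjusted p = 0.00146). The interferon response list rose by a mean of 0.16 over 37 genes (adjusted p = 0.0220, and adjusted p = 0.927 with an estimated correlation), led by the immunoproteasome gene Psmb8 at 0.74 ± 0.25, the antiviral tether gene Bst2 at 0.48 ± 0.17 and Oasl2 at 0.18 ± 0.10. It too turned without treated replicate 4, to a mean of -0.06 (adjusted p = 0.531) with Psmb8 at 0.32, and its call was lost without treated replicate 1 (mean 0.13, adjusted p = 0.230). Heat shock proteins rose by a mean of 0.21 over 16 genes, oxidative phosphorylation genes by 0.06 over 52 and ribosomal protein genes by 0.07 over 56. Their adjusted p were 0.0211, 0.0270 and 0.0211, and adjusted p = 0.927 held for each with an estimated correlation. Hspe1 stood at 0.38 ± 0.15, Hspb1 at 0.62 ± 0.25 and Dnajb1 at 0.40 ± 0.23 among the heat shock genes. Ndufs4 stood at 0.26 ± 0.10, Atp5d at 0.19 ± 0.09 and Ndufa8 at 0.19 ± 0.09 among the respiratory genes. Rps10 stood at 0.53 ± 0.13, Rpl24 at 0.32 ± 0.11 and Rpl39 at 0.27 ± 0.10 among the ribosomal genes. No member of the interferon, heat shock, respiratory and ribosomal lists passed adjusted over the list alone. Leaving out treated replicate 1 ended the heat shock call (mean 0.12, adjusted p = 0.414) and the respiratory call (mean 0.04, adjusted p = 0.316), and so did leaving out replicate 3 (means 0.12 and 0.01, adjusted p = 0.390 and 0.810). Dnajb1 stood at 0.20 without treated replicate 1 and Hspe1 at 0.22 without replicate 3. On arrays 1 to 4 the heat shock mean was 0.44, -0.02, 0.43 and -0.01 in treated and 0.54, -0.29, 0.42 and -0.17 in untreated mutants. The rise thus lay on numbers 1 and 3 in both groups, and whether wild type RNA shared within a number is its source was not tested. Leaving out treated replicate 2 or 4 ended the ribosomal call (means 0.02 and 0.05, adjusted p = 0.687 and 0.205), and leaving out replicate 4 ended the xenobiotic call (mean -0.13, adjusted p = 0.724). Without a dye coefficient the xenobiotic and respiratory calls were lost (adjusted p = 0.0867 and 0.0703) with the means still at -0.19 and 0.06. Without both arrays of number 3 the male-biased call was lost (mean 0.14, adjusted p = 0.0507), and without both of number 2 the cholesterol call (mean -0.14, adjusted p = 0.106).

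**Figure D1:**
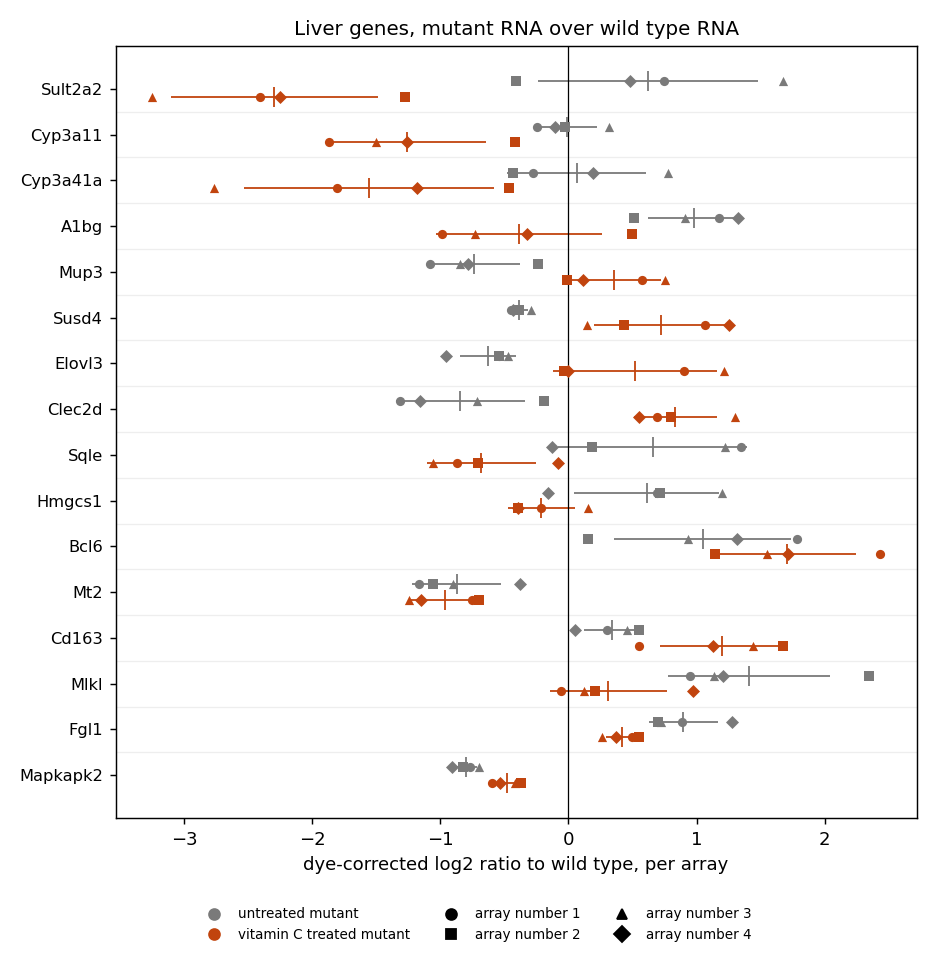
Dye-corrected log2 ratio to wild type (x axis) of 16 named genes (y axis) on each of the 4 untreated and 4 vitamin C treated mutant arrays. Points are arrays, with a marker shape per array number, upright strokes are group means and horizontal bars are ± SD. Sult2a2 lies between -3.25 and -1.28 on the treated arrays and between -0.41 and 1.67 on the untreated ones, while Mt2 lies below 0 on every array. None of these genes passed the test over all genes.

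The third comparison asked how vitamin C treated mutants differed from untreated mutants, each measured against wild type RNA. Its main fit did not use the pairing by number, so variation of wild type RNA shared within a number stayed in each SE and p. No gene passed in limma, the smallest adjusted p was 0.974, and 817 genes had an unadjusted p under 0.05, 452 higher and 365 lower in the treated mice. The other splits of the arrays that part both arrays of every number gave 480 to 670. The genes with the smallest p, none of which passed, were led by Sult2a2 at -2.92 ± 0.49, which is 7.57-fold lower, Sult2a4 at -2.87 ± 0.52 and Clec2d, a C-type lectin, at 1.68 ± 0.27. Clec2d lay between 0.55 and 1.30 on the treated arrays and between -1.32 and -0.19 on the untreated ones. Cyp3a11 stood at -1.25 ± 0.29, A1bg at -1.37 ± 0.32, S1pr1 at -0.96 ± 0.20, Mthfd1l, an enzyme of mitochondrial folate metabolism, at -0.88 ± 0.19, Nr1h5, a nuclear receptor related to FXR, at -0.74 ± 0.16 and Efcab2 at -0.67 ± 0.15. The major urinary protein gene Mup3, a member of a family of near-identical genes, stood at 1.10 ± 0.24. Isoc2a stood at 0.75 ± 0.14, Syne3 at 0.75 ± 0.15, Scrt2 at 0.76 ± 0.15, Prr32 at 0.84 ± 0.17, Tmem213 at 0.62 ± 0.13 and Olfr143 at 0.73 ± 0.16. Wrn stood at -0.03 ± 0.15, Gulo at -0.10 ± 0.15 and Slc23a1 at -0.08 ± 0.16.

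Of the 35 lists, 5 shifted between treated and untreated mutants with the preset correlation and 8 with the wild type number as a block. The cholesterol synthesis list fell by a mean of 0.41 (mean -0.41, adjusted p = 1.3e-06, and adjusted p = 0.962 with an estimated correlation), with 18 of 20 genes below 0. Sqle stood at -1.34 ± 0.36, Cyp51 at -0.60 ± 0.20 and Hmgcs1 at -0.82 ± 0.28, and no member passed adjusted over the list alone. The female-biased list fell by a mean of 0.46 (mean -0.46, adjusted p = 1.6e-05, and adjusted p = 0.399 with an estimated correlation), with 19 of 25 genes below 0 and 2 passing adjusted over the list alone. Its leading members were Sult2a2, A1bg and Cyp3a41a at -1.62 ± 0.46. The male-biased list rose by a mean of 0.33 over 22 genes, 19 of them above 0 and 4 passing adjusted over the list alone (adjusted p = 0.000217, and adjusted p = 0.962 with an estimated correlation). Mup3 was joined by Susd4 at 1.11 ± 0.24 and Elovl3, a fatty acid elongase gene, at 1.15 ± 0.29. Oxidative phosphorylation genes rose by a mean of 0.11, with 40 of 52 above 0 (adjusted p = 0.00545, and adjusted p = 0.962 with an estimated correlation), led by Atp5d at 0.33 ± 0.12, Ndufa8 at 0.28 ± 0.13 and Ndufb8 at 0.29 ± 0.13. Ribosomal protein genes rose by a mean of 0.12, with 43 of 56 above 0 (adjusted p = 0.00764, and adjusted p = 0.962 with an estimated correlation), led by Rps19 at 0.31 ± 0.13, Rpl10a at 0.38 ± 0.16 and Rps21 at 0.36 ± 0.16. No respiratory or ribosomal gene passed adjusted over the list alone.

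The 3 lists added by the block were the erythroid markers (mean 0.35, adjusted p = 2.4e-06), the Kupffer cell and macrophage markers (mean 0.38, adjusted p = 0.000224) and the ER stress list (mean -0.10, adjusted p = 0.0168). With an estimated correlation, without the block, their adjusted p were 0.962, 0.968 and 0.962, and with the preset correlation 0.167, 0.167 and 0.119. Treated minus untreated within a number, the macrophage mean was -0.01, 0.12, 0.08 and 1.34 for numbers 1 to 4, a mean of 0.06 without number 4. The calls of the cholesterol, female-biased and male-biased lists held with any 1 array left out, although the mean of the list cholesterol synthesis, vitamin C treated over untreated mutant, was -0.24 without untreated replicate 3. Within numbers 1 to 4 the cholesterol difference was -0.40, -0.45, -0.83 and 0.05, so it did not fall in number 4. The female-biased difference was -0.55, -0.13, -0.71 and -0.44. The male-biased difference was 0.54, -0.05, 0.42 and 0.42, so it did not rise in number 2. The respiratory call was lost without untreated replicate 2 (mean 0.09, adjusted p = 0.0715) or 4 (mean 0.09, adjusted p = 0.0659), and without treated replicate 1 (mean 0.09, adjusted p = 0.0810) or 3 (mean 0.06, adjusted p = 0.283). The ribosomal call was lost without untreated replicate 1 (mean 0.08, adjusted p = 0.163) or 3 (mean 0.05, adjusted p = 0.549), and without treated replicate 2 (mean 0.07, adjusted p = 0.327) or 4 (mean 0.10, adjusted p = 0.0580). Other splits of the 8 arrays gave up to 16 shifted lists.

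With the values turned by the dyes, other lists shifted and several changed direction. In untreated mutants 7 lists then shifted against wild type and in treated mutants 8, led in both by the hepatocyte markers, at a mean of 0.34 (adjusted p = 6.8e-07) and 0.35 (adjusted p = 2.4e-09). With an estimated correlation their adjusted p were 0.0610 and 0.0309, and no other list had one under 0.05. PPAR alpha targets and fatty acid oxidation genes then stood at means of 0.20 and 0.13, antioxidant and NRF2 targets at 0.14 and 0.18, xenobiotic metabolism at 0.20 and 0.31, ribosomal protein genes at -0.12 and -0.11 and macrophage markers at 0.71 and 0.39, all with an adjusted p under the threshold by the preset correlation. So did the interferon response in untreated mutants (0.26) and, in treated mutants, the acute phase list (0.24) and the female-biased list (0.28). The female-biased, xenobiotic and ribosomal lists were thus called in the opposite direction in treated mutants. Of the lists called as deposited, both in untreated mutants and all 5 between treated and untreated mutants lost their call. Only the interferon response shifted between treated and untreated mutants (mean -0.20, adjusted p = 0.00681, and adjusted p = 0.994 with an estimated correlation). Genes that passed in both groups under that reading were Enpep, an aminopeptidase, at 0.85 ± 0.11 and 0.85 ± 0.11 and the catalase gene Cat at 1.21 ± 0.15 and 1.24 ± 0.15. Ehhadh, an enzyme of peroxisomal fatty acid oxidation, passed in untreated mutants at 1.09 ± 0.13. Under that reading the mean change of both groups equals the dye coefficient of the values as deposited. Of the 220 genes that passed for both groups averaged, 218 had a dye effect as deposited. For genes and lists that shift alike in both groups, a dye effect and a mutant change are thus not told apart.

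**Figure D2:**
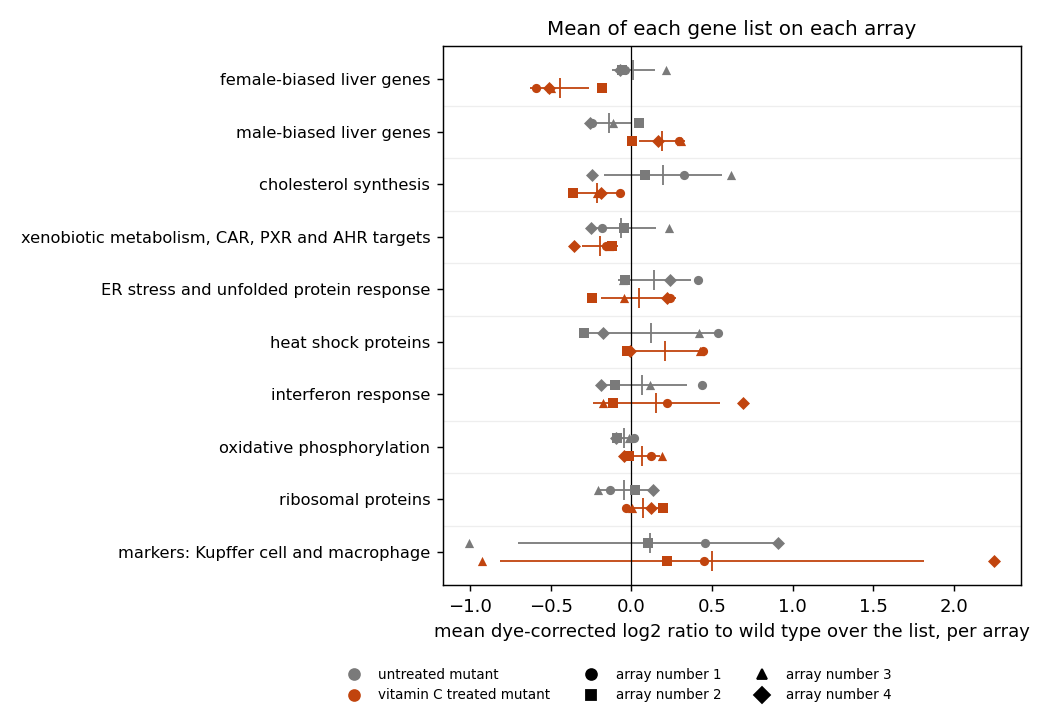
Mean dye-corrected log2 ratio to wild type (x axis) of 10 gene lists (y axis) on each array. Points are arrays, with a marker shape per array number, upright strokes are group means and horizontal bars are ± SD over the 4 arrays. The female-biased list lies between -0.59 and -0.18 on the treated arrays and between -0.07 and 0.21 on the untreated ones, and the macrophage markers range from -1.01 to 2.25 with both arrays of a number on the same side of 0. The male-biased list overlaps, between 0.00 and 0.31 on the treated arrays and between -0.25 and 0.05 on the untreated ones.

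Across genes, which are not independent replicates, the changes of untreated and treated mutants against wild type had a Pearson correlation of 0.27. Unchanged groups that share the wild type RNA of each number gave 0.33 in simulation. The covariance was 0.00925, against 0.00939 in the simulation. When the 2 changes were taken from different wild type numbers, the mean correlation over 4 splits was -0.01, with a range of -0.05 to 0.03. At an unadjusted p under 0.05, 91 genes were higher in both groups and 142 were lower in both, where independent lists would share 22.3 and 29.9. Unchanged groups sharing wild type RNA gave means of 104 and 104 in 50 simulations, with ranges of 71 to 130 and 81 to 140. 26 genes had opposite signs, against 21.6 in simulation. The simulated groups had a mean of 1162 genes at that p for untreated mutants and 1161 for treated mutants, above 954. The change from untreated to treated mutants had a correlation of -0.07 with the change of untreated mutants against wild type when the 2 came from different array numbers (range -0.09 to -0.03 over 4 splits), against 0.00 in simulation. With all arrays in both changes it was -0.61, against -0.58 for unchanged groups, since the untreated arrays enter both with opposite signs.

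Of the 37 genes listed beforehand as neighbours of Wrn on chromosome 8, 34 were measured. As a list they did not shift in either group (adjusted p = 0.957 in untreated and 0.885 in treated mutants), and members lay on both sides of 0. Adjusted over the list alone, 1 was higher and 2 were lower in the untreated mutants, and 3 were higher and 3 lower in the treated mutants. With both groups averaged, a comparison chosen after the data had been seen, no gene passed over all genes at 0.05 and 5 had an adjusted p under 0.10, which were Mapkapk2 at -0.64 ± 0.07, Plac9a at -0.83 ± 0.09, Mfhas1 at 0.69 ± 0.09, Mt2 at -0.92 ± 0.12 and Slc25a15 at -0.70 ± 0.09. Mfhas1 and Slc25a15 lie within 100 measured genes of Wrn. The count of genes in that window chose the reading of the values. The counts adjusted over the list alone and these 2 genes are thus no independent evidence of a change near Wrn.

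**Figure D3:**
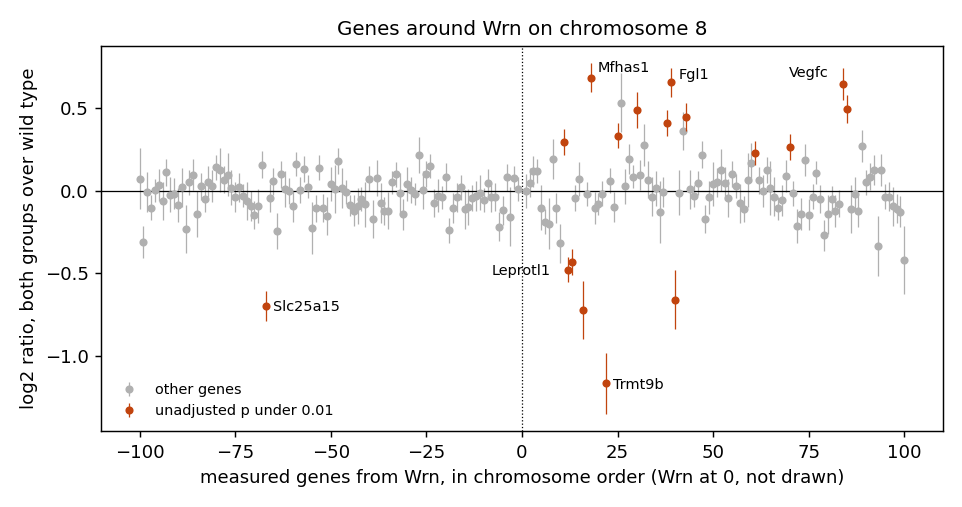
Mean log2 ratio of both mutant groups over wild type (y axis, ± SE) of the 100 measured genes on each side of Wrn, by their order on chromosome 8 (x axis). Genes with an unadjusted p under 0.01 are in orange, and 16 of the 17 lie after Wrn, with values such as 0.66 for Fgl1, 0.65 for Vegfc, -0.48 for Leprotl1 and -1.17 for Trmt9b. The count of these genes chose the reading of the values, so it is no independent evidence of a change near Wrn.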

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

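No test in this part was chosen after its result was seen. In 125 groups of 4 arrays, for named genes and called lists, 4 held an array far from the others by Dixon's criterion, where chance gives about 6.25. Mrpl22 stood at 0.51 on treated replicate 4 and between 0.43 and 0.44 on the other treated arrays, a small gap among close values. Elovl3 stood at -0.96 on untreated replicate 4 and between -0.54 and -0.47 on the other untreated arrays. The xenobiotic metabolism list had a mean of -0.36 on treated replicate 4, against -0.16 to -0.12 on the others, and its call was lost without that array. The female-biased liver list had a mean of 0.21 on untreated replicate 3 and between -0.07 and -0.04 on the other untreated arrays.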

How the results depend on the processing

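Leaving out both arrays of a wild type number, the Cy5 over Cy3 reading of the lists, and each alternative for the mean of both groups, were chosen after the data were seen. With no dye coefficient, median centring, scale normalization, array weights, robust eBayes, each group's arrays alone, a test per feature, an adjusted p under 0.10 and the replicate block, 0 genes passed in each of the 3 comparisons where that alternative applies. The test per feature gave 3409, 3055 and 1945 of 45220 features at an unadjusted p under 0.05. Read as Cy5 over Cy3, the values gave 9 genes for untreated and 10 for treated mutants over wild type. It gave 7, 8 and 1 lists in place of 2, 9 and 5. The cholesterol list turned to -0.0080 in untreated mutants. In treated mutants over wild type the xenobiotic list turned to 0.31, the female-biased to 0.28, the respiratory to -0.057 and the ribosomal to -0.11. Between treated and untreated mutants the male-biased list turned to -0.085, the female-biased to 0.12 and the respiratory to -0.018. Of the 25, 42 and 31 named genes, 10, 24 and 19 had the opposite sign. Which reading is right was not settled. With the replicate block 8 lists shifted between treated and untreated mutants in place of 5, and the block changed no other count of genes or lists in the 3 comparisons by more than 1.5 times. An estimated correlation and fry each gave 0 lists in all 3 comparisons. The first uses the correlation seen between members, 0.456 over all arrays for the cholesterol list, in place of 0.01. Over fits that left out an array, or both arrays of a number, the genes called ranged from 0 to 15 for untreated and 0 to 8 for treated mutants over wild type, with the highest without both arrays of number 4. They stayed at 0 between treated and untreated mutants. The lists called ranged from 0 to 10 for untreated mutants over wild type, 6 to 13 for treated mutants over wild type and 5 to 9 between treated and untreated mutants. The correlation of the changes against wild type ranged from 0.14 to 0.40 over these fits and was -0.013 with the wild type numbers split. The correlation of the vitamin C difference with the mutant change was -0.61 with all arrays in both, where the untreated arrays enter with opposite signs. Without treated replicate 4 the macrophage markers turned to -0.20 and the interferon list to -0.058 in treated mutants over wild type. Without both arrays of a number these lists ranged from -0.30 to 1.19 and from -0.046 to 0.29. Between treated and untreated mutants, Wrn changed sign to 0.0067 without untreated replicate 1, 0.041 without untreated replicate 4 and 0.040 without treated replicate 4. Without both arrays of a number Wrn ranged from -0.14 to 0.087, Gulo from -0.22 to 0.0053 and Slc23a1 from -0.25 to 0.00096. The causes of the changes with left-out arrays were not tested. For both groups averaged over wild type, 0 genes passed, 5 at an adjusted p under 0.10, 2 without the block and 220 read as Cy5 over Cy3. Missing values were not an alternative because there were none, and a filter on dim features was not run because no intensity is in the table, so signal over background sets a limit that is unknown here.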

Other observations

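The tests of the Wrn region, of sex, of single arrays and of marker genes in this part were chosen after the results they bear on had been seen, and the splits that count genes and lists were planned before.

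The genes of this paragraph were chosen after their values were seen, Mt2, Bcl6 and Erdr1 among them also named for the treated mutants, and none passed over all genes. The metallothionein gene Mt1 stood at -0.61 ± 0.15 in untreated and -0.81 ± 0.15 in treated mutants, beside Mt2 at -0.87 ± 0.15 and -0.96 ± 0.15. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at -1.12 ± 0.37 and -2.01 ± 0.37, and Cish, a feedback inhibitor of cytokine signalling through STAT5, at -0.90 ± 0.21 and -0.81 ± 0.21. Bcl6 stood at 1.05 ± 0.26 in untreated mutants, and Erdr1 at -1.30 ± 0.39. Cyp8b1, which makes cholic acid, stood at -1.89 ± 0.39 in untreated and -0.30 ± 0.39 in treated mutants, a difference of 1.58 ± 0.56 with an adjusted p of 0.974. The bile acid synthesis and transport list did not shift, with a mean of -0.08 in untreated mutants (adjusted p = 0.906, 9 genes above 0 and 9 below), -0.07 in treated mutants (0.885) and 0.00 between them (0.973). Because both groups were measured against the same wild type numbers, signs shared by the groups are not independent. The gluconeogenesis, glycolysis and insulin signalling list had a mean of -0.20 in untreated mutants and missed the threshold (adjusted p = 0.0585). Lists of DNA repair and RecQ helicases (mean 0.03, adjusted p = 0.639), p53 targets (0.00, 0.803), antioxidant and NRF2 targets (0.03, 0.801), hypoxia targets (-0.04, 0.972) and ascorbate genes (-0.02, 0.933) did not shift in untreated mutants. Nor did markers of hepatocytes (-0.01, 0.933), liver endothelium (-0.06, 0.642), bile duct (0.04, 0.626), lymphocytes (0.09, 0.188), neutrophils (-0.08, 0.933), red cells (-0.28, 0.336), adipose tissue (0.00, 0.957) or pancreas (-0.05, 0.780).

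No gene within 100 measured genes of Wrn on chromosome 8 passed for both groups averaged (smallest adjusted p = 0.0820), but 17 had an unadjusted p under 0.01, 1 before Wrn and 16 after it, from the gene at place 11 to that at place 85. As many were held by 0.852% of windows of this size, 128 windows that all lie on chromosome 8, and the most, 19, by windows centred 88 to 112 places after Wrn. The reading of the values was chosen from this count. Neither this count nor that for the dye coefficient, which 45.6% of windows reached, can thus exclude a chance location or a dye effect. Poor binding of mutant alleles that differ from the probes would move the genes a single way. Of the 17, 11 were higher and 6 lower, so the rarer direction held 35.3%. As these same genes chose the reading of the values, their signs do not decide whether poor binding had a part. A segment of donor strain DNA that stayed beside the mutation is a candidate explanation, but the labels give C57Bl/6 throughout and no group to test it, so no biological explanation was tested.

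Sex-biased liver genes separated treated from untreated mutants, with the male-biased mean 0.79 above the female-biased mean in the difference, but at -0.085 against 0.12 with the values turned by the dyes. In number 2 the lists lay close, at -0.05 for the male-biased and -0.13 for the female-biased difference. The mean of 3 Y-linked genes stayed within 0.19 of 0 on every array. The SD over these genes was 0.48 on untreated replicate 3 and 0.34 on treated replicate 3. The mean speaks against different sexes on the same array only if the features detect RNA, which cannot be checked without intensities. Sexes that differed between numbers but matched on each array would also give ratios near 0. Untreated replicate 3 had both the lowest Y-linked mean (-0.19) and the highest Xist (0.95). The lowest Xist, -0.63, was on treated replicate 3. A single array as the source was argued against, since the female-biased mean was still -0.38 with the most influential array left out. It was -0.20 without its 5 genes of smallest p. Chance could not be excluded, since 2 of 34 splits of the 8 arrays separated the lists as much, the highest other split by 0.81, and a vitamin C effect stays open as a hypothesis. Among the 8 splits that part both arrays of every number, the real split was the largest, with 0.75 next, and 8 splits cannot give a share under 0.05.

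The mean of the macrophage markers ranged from -1.01 to 2.25 over the arrays, with both arrays of each number on the same side of 0. The wild type animal of each number may be the source, since the shared part was 0.882 of the variance of the list's mean. A lower share of hepatocytes in a sample would raise markers of other liver cells together. Between treated replicates 4 and 3 the macrophage markers differed by 3.18 ± 0.51 (SE over 18 genes). The bile duct markers differed by -0.16 ± 0.11, so they did not rise as predicted. Lymphocyte markers (1.02 ± 0.26), matrix and stellate cell genes (0.63 ± 0.12) and endothelial markers (0.55 ± 0.17) went the way a lower share needs. Hepatocyte markers differed by -0.14 ± 0.10. Pancreas markers, which are not of liver cells, differed by -0.07 ± 0.06 and bear little on it. The lists disagree and rest on a single pair of arrays, so they do not decide whether a lower share had a part. The excess of treated replicate 4 over its untreated partner, 2.25 against 0.91, stays open, and vitamin C as its source was not tested.

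Other splits of the arrays bear on the counts. Flipping the signs of the arrays of a group gives 8 splits, too few for a share under 0.05. For genes, the real count was 0 in both groups and the highest other 0, and with a real count of 0 any split gives as many (8 of 8), which says nothing of chance. At an unadjusted p under 0.05 the real split had the most genes in both, 1487 with 1271 next in untreated and 1354 with 1144 next in treated mutants. For lists, untreated mutants had 2 and the highest other 12 (6 of 8 as many), and treated mutants had 9 and the highest other 15 (4 of 8 as many). Between treated and untreated mutants, 34 of the 35 splits could be fitted, since the remaining split is the dye swap. The real count of genes was 0 and the highest other 1, so that 34 of 34 giving as many again says nothing of chance. The real count of lists was 5 and the highest other 16, and 25 of 34 gave as many, so chance was not excluded. The 26 splits that kept both arrays of at least 1 number together gave a median of 9 lists. Splits that part every pair also have the dyes balanced, which not all of the 26 have. Shared wild type RNA and dye balance are thus not told apart. Among the 8 splits that parted every pair, the real 5 lists were the most, with 4 next. So were the real 817 genes at an unadjusted p under 0.05, with 670 next, but 5% of the genes tested is about 954, above all of these splits.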
